A study of Mus musculus with 21 samples.

How the data were processed

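RNA was sequenced from bone marrow c-kit+ cells of C57BL/6 mice. Per the labels' protocols, marrow was flushed from femur and tibia, red cells were lysed, and cells binding CD117 (c-kit, the stem cell factor receptor of blood progenitors) were enriched with magnetic beads. Each RNA-seq library carries 1 of 4 genotype labels: 3 libraries are Asxl1-/-Jak2V617F, 3 are Jak2V617F, 2 are Asxl1-/- and 3 are WT. Chromatin accessibility and histone mark samples of the series were not analysed here.

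The deposited values are raw read counts per Ensembl gene, with 1 column per library, 54532 genes and 11 libraries. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.16.1, Bowtie2 2.2.9, MACS 1.4.253, deepTools and the mm10 genome, without roles or order. The strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Counts of genes with near-identical copies or pseudogenes, and of antisense or overlapping genes, are therefore uncertain. Coordinates are those of the deposited table.

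Total counts ranged from 16198011 to 19196283 per library. Replicates of a group differed by 8.44 to 37 times sampling noise (chi-square over genes per degree of freedom), so each was kept as its own sample. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

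Genes were filtered with filterByExpr by group, which left 16262 genes. Counts were scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test with robust dispersion. All 11 libraries entered 1 fit with a genotype factor, which gave a common biological coefficient of variation of 19.7% and a median prior degrees of freedom of 4.64. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Log2 fold changes are given ± a standard error derived from the test, their absolute value over the square root of the quasi-likelihood F statistic. CPM values (counts scaled to library size and TMM factor) are given as mean ± SD. The 5 comparisons and the interaction, which asks whether the effect of Asxl1 loss differs between the Jak2V617F and WT backgrounds, are contrasts of this fit.

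Before the data were examined, 22 gene lists were fixed: stem cell, erythroid, megakaryocyte, primary granule, late neutrophil, monocyte and macrophage, mast cell and basophil, eosinophil, B lymphoid, T and NK, dendritic cell and MHC class II, stroma, JAK-STAT target, interferon, TNF and NF-kB, immediate early, fibrosis and matrix, Hox, Polycomb and BAP1, cell cycle, p53 target and cholesterol synthesis. The lists share 11 genes, each in 2 lists, among them Meis1, Hoxa9 and Hoxb4 in the stem cell and Hox lists. Each list was tested 2-sided with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Camera compares a list with the other genes. It was repeated with a correlation estimated from the data, under which none of the 132 list tests passed after adjustment, while 8 had an unadjusted p under the threshold. The fry test, which asks whether a list moves on balance one way and compares it with no other genes, was run beside it. Counts of genes that rose or fell are also given adjusted over the list alone.

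Genes are named by a rule fixed before the data were examined. Per comparison it takes the 10 rising and 10 falling protein-coding genes of largest change with a mean CPM of 2 or more and no overlap between the groups' libraries, up to 4 members of each list with the smallest adjusted p, and always Asxl1, Jak2, Egr1 and Tnf. Egr1 and Tnf are in the rule because a published study of these mice is recalled to deal with them. For the interaction it takes the 10 genes of smallest adjusted p. Some genes that the rule takes are not reported here.

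The test was run on simulated counts with known changes. Each comparison had a single draw of independent genes, with 100 genes changed at each fold in a single group and all others alike. Far more genes were called in the data, so the counts below do not carry over to them. In the simulation of Asxl1-/-Jak2V617F against Jak2V617F it recovered 52 of 98 genes changed 2-fold and 76 of 98 changed 4-fold, and called 8 of the other genes among 15678 tested. For Jak2V617F against WT it recovered 45 of 98 and 80 of 95, with 12 others called among 15692. For Asxl1-/- against WT it recovered 48 of 98 and 65 of 97, with 0 others called among 15672. For Asxl1-/-Jak2V617F against WT it recovered 59 of 99 and 80 of 95, with 5 others among 15694. For Asxl1-/-Jak2V617F against Asxl1-/- it recovered 39 of 98 and 74 of 99, with 3 others among 15712.

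Alternatives fixed before the data were examined were DESeq2 1.42.0, median-of-ratios scaling, no or a stricter filter (CPM of 1 in 3 libraries), a fit of the compared groups alone, a replicate number block, an added 2-fold threshold, and leaving out each library. Added after the data were seen were a sex term (libraries with reads on Y-linked genes against the rest), the restriction to protein-coding genes, and lists of heat shock and resident macrophage genes. One technical check, of a trend with exonic length, fell between the bounds written for it, and a further test that removes the trend was added after that value was seen. The further test for a time stood in place of the first one, which was then put back with its bounds as written.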

Results

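The data are RNA-seq counts of c-kit+ bone marrow cells, a fraction rich in blood stem and progenitor cells. Asxl1 encodes a chromatin regulator that works with the BAP1 deubiquitinase, and Jak2V617F is the activated form of the Jak2 kinase found in myeloproliferative neoplasms. The 4 genotypes were Asxl1-/-Jak2V617F (n = 3), Jak2V617F (n = 3), Asxl1-/- (n = 2) and WT (n = 3), with 16198011 to 19196283 counts per library.

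Asxl1 (ENSMUSG00000042548, mm10 chromosome 2, 153345829 to 153404007) was lower in both Asxl1-/- genotypes. Its level was 96.4 ± 3.61 CPM in Asxl1-/-Jak2V617F (n = 3) and 93.0 ± 5.66 CPM in Asxl1-/- (n = 2), against 157 ± 34.4 CPM in Jak2V617F (n = 3) and 162 ± 1.41 CPM in WT (n = 3). By edgeR's quasi-likelihood test it fell by 0.70 ± 0.12 on the log2 scale in Asxl1-/-Jak2V617F against Jak2V617F (adjusted p = 0.000748) and by 0.80 ± 0.14 in Asxl1-/- against WT (adjusted p = 0.0042). The latter call was lost without Asxl1-/- 1 (adjusted p = 0.071) and with a sex term (adjusted p = 0.136). In Jak2V617F against WT Asxl1 did not pass (-0.05 ± 0.12, adjusted p = 0.74), but did without Jak2V617F 1 (-0.24, adjusted p = 0.0272). Gene-level counts sum all exons, and the exons removed by the allele are not given in the sources used here. Jak2 (ENSMUSG00000024789, chromosome 19, 29251828 to 29313080) was 126 ± 3.94 CPM in Jak2V617F, 92.2 ± 5.64 in Asxl1-/-Jak2V617F, 101 ± 2.22 in Asxl1-/- and 77.0 ± 5.93 in WT. Gene counts do not show which allele of Jak2 was read.

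**Figure D1:**
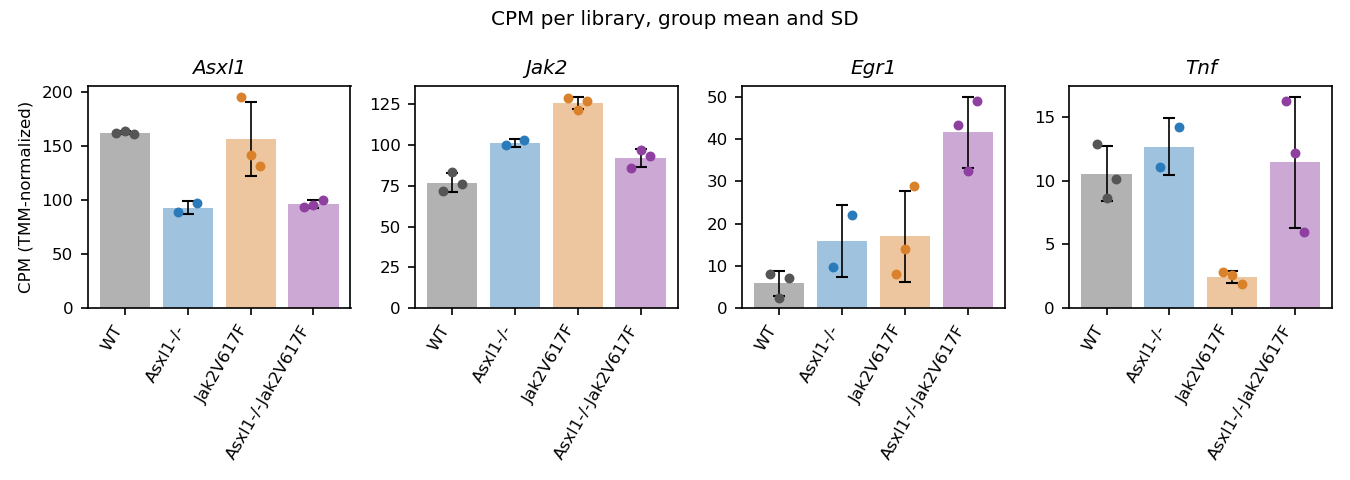
CPM (TMM-normalized) of Asxl1, Jak2, Egr1 and Tnf in each library, by genotype, with points for libraries, bars for group means and error bars for SD. Asxl1 averaged 96.4 and 93.0 CPM in the 2 Asxl1-/- genotypes and 157 and 162 CPM in the other 2.

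The Jak2V617F libraries stood apart from all others. The main axis of a principal component analysis of log2 CPM, with 51.5% of the variance, placed them at 98.5 to 105 and the other 8 libraries at -47.3 to -17.8. A sum of 10 granule genes took 0.268 to 0.591% of counts in Jak2V617F and 4.01 to 6.27% in every other library. They were S100a8, S100a9, Ngp, Ltf, Camp, Lcn2, Elane, Mpo, Prtn3 and Ctsg. All belong to the primary granule or late neutrophil lists, so the sum is not independent of those lists. It was not among the shares planned beforehand. Haemoglobin genes took 0.00538 to 0.11% of counts, with the highest share in Jak2V617F 2, and mitochondrially encoded genes 1.17 to 1.9%. Kit itself lay between 218.8 and 338.3 CPM across all libraries. Reads on Y-linked genes were found in both Asxl1-/- libraries (192 and 194 CPM) and in Jak2V617F 2 (248 CPM), while the remaining libraries had Xist at 1390 to 2150 CPM. The sex of the mice was therefore not the same across groups.

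**Figure D2:**
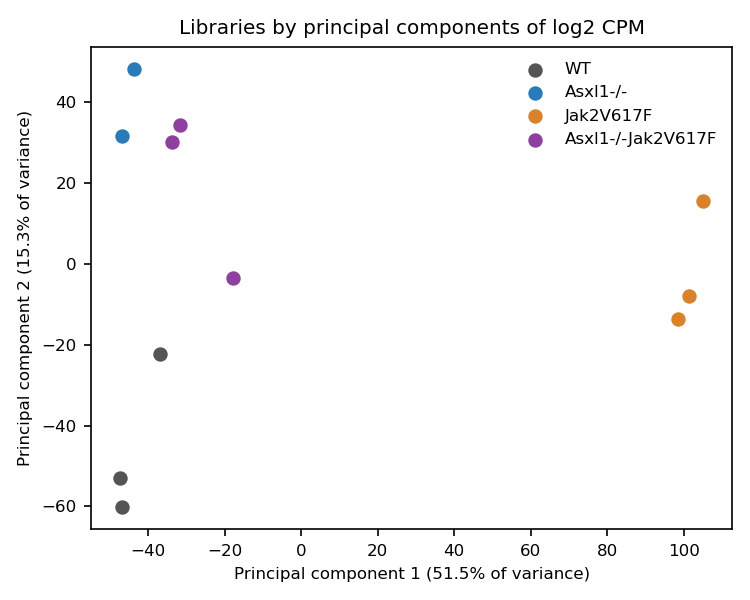
Principal components 1 (51.5% of variance, horizontal) and 2 (15.3%, vertical) of log2 CPM, each point a library coloured by genotype. The Jak2V617F libraries lie at 98.5 to 105 on the horizontal axis and all others at -17.8 or below.

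The main comparison asks what loss of Asxl1 does to Jak2V617F cells. Granulocyte genes were far higher in Asxl1-/-Jak2V617F than in Jak2V617F, and erythroid and antigen presentation genes were lower. All 14 primary granule genes rose (median log2 3.87), among them Mpo, the myeloperoxidase of azurophil granules (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413; 4.26 ± 0.28), Ctsg, a granule serine protease (4.38 ± 0.28), and Prss57 (4.56 ± 0.24). All 19 late neutrophil genes rose as well (median 2.84), such as the calprotectin subunit S100a8 (3.09 ± 0.32), the antimicrobial peptide gene Camp (3.04 ± 0.31) and Lcn2, which sequesters iron-binding siderophores (2.54 ± 0.28). Of 24 erythroid genes 21 fell and 3 did not pass (median -1.58), including the erythropoietin receptor Epor (-1.71 ± 0.21) and Rhag of the Rhesus complex (-1.87 ± 0.28). These 3 counts were the same adjusted over the list alone. Camera gave adjusted p = 7.61e-11 for primary granule, 1.45e-08 for late neutrophil and 2.15e-08 for erythroid genes. The 3 values were an adjusted p = 0.289, 0.335 and 0.325 with an estimated correlation.

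Other lineages moved too. Of 10 eosinophil genes 8 rose and 1 fell (median 3.64, camera adjusted p = 0.000506, and adjusted p = 0.325 with an estimated correlation). Prg2, the granule major basic protein, rose by 3.84 ± 0.30 and the surface lectin Siglecf by 3.14 ± 0.15. Of 12 mast cell and basophil genes 7 rose and none fell (8 and 0 adjusted over the list alone; median 1.80, adjusted p = 0.00314, and adjusted p = 0.289 with an estimated correlation). The mast cell carboxypeptidase Cpa3 rose by 2.37 ± 0.16 and the basophil protease Mcpt8 by 2.67 ± 0.31. Of 22 megakaryocyte and platelet genes 14 rose and 1 fell (median 0.99, adjusted p = 0.000987, and adjusted p = 0.289 with an estimated correlation). Among them were the ETS factor Fli1 (2.40 ± 0.19) and the integrin Itga2b (1.53 ± 0.17). Of 19 stem cell genes 10 rose and 1 fell (median 1.26, adjusted p = 0.00803, and adjusted p = 0.325 with an estimated correlation). Cd34, a surface protein of progenitors, rose by 2.97 ± 0.17 and the transcription factor Hlf by 2.43 ± 0.24, while Mllt3 fell (-1.20 ± 0.16). Of 15 dendritic cell and MHC class II genes 10 fell and 1 rose (12 and 1 adjusted over the list alone; median -2.80, adjusted p = 8.73e-05, and adjusted p = 0.325 with an estimated correlation). The MHC class II chain H2-Ab1 (-2.87 ± 0.24) and its chaperone Cd74 (-3.13 ± 0.26) fell, and the transcription factor Runx2 rose (2.05 ± 0.15). Of 15 T and NK genes 11 fell and 1, Nkg7, rose (12 and 1 adjusted over the list alone; median -2.01, adjusted p = 0.00254, and adjusted p = 0.373 with an estimated correlation). Of 17 B lymphoid genes 6 rose, such as Dntt (3.16 ± 0.46), and 2 fell, Cd22 and Ms4a1. The B lymphoid median was -0.27, its mean 0.22 and camera's direction down (adjusted p = 0.816).

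Of 22 monocyte and macrophage genes 9 rose and 1 fell (median 0.79, camera adjusted p = 0.0208, and adjusted p = 0.492 with an estimated correlation), including Ly6c2 of inflammatory monocytes (3.37 ± 0.28) and the endotoxin co-receptor Cd14 (3.41 ± 0.39). That list call was lost without Asxl1-/-Jak2V617F 3 (adjusted p = 0.0527) and without Jak2V617F 3 (adjusted p = 0.0789). Of 17 fibrosis and matrix genes 10 rose and 3 fell (median 1.89, adjusted p = 0.0406, and adjusted p = 0.325 with an estimated correlation). The intermediate filament gene Vim rose by 2.51 ± 0.13, the angiogenic factor Vegfa by 2.07 ± 0.14 and osteopontin (Spp1) by 3.21 ± 0.38. The list call was lost without Jak2V617F 1 (adjusted p = 0.083) or Jak2V617F 3 (adjusted p = 0.0589) and with the replicate block (adjusted p = 0.057). Of 8 measured stroma genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; median 2.16, adjusted p = 0.0442, and adjusted p = 0.337 with an estimated correlation). This call was lost without Asxl1-/-Jak2V617F 1 (adjusted p = 0.071) or Jak2V617F 3 (adjusted p = 0.129), with the stricter filter (adjusted p = 0.059) and with the replicate block (adjusted p = 0.057).

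Signalling and chromatin lists gave a mixed account. Of 20 immediate early genes 13 rose and none fell (median 1.5, camera adjusted p = 0.000905, and adjusted p = 0.337 with an estimated correlation), among them Ier2 (1.72 ± 0.15), Klf6 (2.05 ± 0.23) and Fos (2.84 ± 0.45). Egr1, a growth factor-induced transcription factor (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), was 41.7 ± 8.46 CPM in Asxl1-/-Jak2V617F and 17.0 ± 10.8 CPM in Jak2V617F, a difference of 1.29 ± 0.54 that did not pass (adjusted p = 0.0801) but did without Jak2V617F 3 (adjusted p = 0.0194). Of 11 Hox list genes 7 rose (median 1.31, adjusted p = 0.00314, and adjusted p = 0.325 with an estimated correlation), such as Meis1 (1.47 ± 0.19), Hoxa9 (1.26 ± 0.20) and Hoxb4 (1.31 ± 0.24). The genes named here are also in the stem cell list, so the calls of both lists rest partly on the same genes. Of 19 TNF and NF-kB genes 8 rose and 3 fell (10 and 3 adjusted over the list alone; adjusted p = 0.193, and 0.0184 by fry). The cytokine gene Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) rose from 2.43 ± 0.484 to 11.4 ± 5.15 CPM (2.23 ± 0.34, adjusted p = 0.000255), the neutrophil chemokine gene Cxcl2 rose by 5.39 ± 0.87, and the TNF receptor adaptor Traf1 fell (-4.07 ± 0.37). Of 25 interferon genes 7 rose (5 adjusted over the list alone; adjusted p = 0.0646), a list test that passed without Asxl1-/-Jak2V617F 1 (0.0261), without Jak2V617F 2 (0.0349) and with the replicate block (0.0374). Of 16 JAK-STAT targets 6 rose and 2 fell (6 and 3 adjusted over the list alone; adjusted p = 0.676), with Stat3 at 1.19 ± 0.14 and the kinase gene Pim1 at 1.10 ± 0.21. Of 30 Polycomb and BAP1 genes 8 rose and 11 fell (9 and 12 adjusted over the list alone; adjusted p = 0.383). The Polycomb subunit gene Pcgf5 (1.21 ± 0.09) rose and Cbx7 (-1.39 ± 0.24) fell. Of 27 cell cycle genes 5 rose and 2 fell (2 and 1 adjusted over the list alone; adjusted p = 0.758). Of 16 p53 targets 5 rose and 5 fell (6 and 6 adjusted over the list alone; median -0.31, mean 0.31, adjusted p = 0.676). Of 20 cholesterol synthesis genes 4 rose and 3 fell (3 and 3 adjusted over the list alone; adjusted p = 0.73).

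Across all genes, 7209 changed, 3985 higher and 3224 lower, of which 2217 and 1291 differed at least 2-fold. Large rises outside the lists included the keratinocyte-secreted Dmkn (24.7 ± 10.6 against 0.748 ± 0.213 CPM), the macrophage lectin Mgl2 (50.4 ± 21.1 against 1.92 ± 0.644 CPM) and the secreted chaperone clusterin, Clu (4.96 ± 0.72). Large falls included Dnase1l3, a secreted endonuclease (0.809 ± 0.338 against 47.1 ± 15.0 CPM), the Notch regulator Dtx1 (-5.84 ± 0.54), Adam23 (-5.79 ± 0.52) and the complement receptor Cr2 (-5.65 ± 0.79).

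The comparison of Jak2V617F with WT sets cells labelled with the activated kinase alone beside cells with neither lesion. Erythroid genes were higher and granulocyte, monocyte, eosinophil, mast cell, stem cell and megakaryocyte genes lower. Of 24 erythroid genes 22 rose (median 1.60, camera adjusted p = 6.16e-08), such as Epor (1.67 ± 0.21), the transferrin receptor Tfrc (2.01 ± 0.25) and the erythroid transcription factor Klf1 (1.65 ± 0.24). All 14 primary granule genes fell (median -3.67, adjusted p = 2.56e-08), with Mpo at -3.70 ± 0.27. All 19 late neutrophil genes fell (median -3.42, adjusted p = 3.63e-08), with Camp at -3.84 ± 0.32. These 3 counts were the same adjusted over the list alone, and the tests gave adjusted p = 0.254, 0.254 and 0.295 with an estimated correlation. The comparison uses the same Jak2V617F libraries as the one with Asxl1-/-Jak2V617F, so that opposite signs in both rest partly on shared values.

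Of 22 monocyte and macrophage genes 19 fell (20 adjusted over the list alone; median -1.99, camera adjusted p = 2.77e-05, and adjusted p = 0.254 with an estimated correlation). Among them were the lysozyme gene Lyz2 (-3.67 ± 0.37) and the chemokine receptor Ccr2 (-2.29 ± 0.33). Of 10 eosinophil genes 9 fell (median -2.88, adjusted p = 0.000427, and adjusted p = 0.254 with an estimated correlation). Of 12 mast cell and basophil genes 8 fell (1 rose and 8 fell adjusted over the list alone; median -2.35, adjusted p = 0.00931, and adjusted p = 0.254 with an estimated correlation). Of 22 megakaryocyte genes 16 fell (18 adjusted over the list alone; median -1.95, adjusted p = 4.27e-05, and adjusted p = 0.193 with an estimated correlation), including Fli1 (-2.45 ± 0.19) and Mmrn1 (-2.91 ± 0.24). Of 19 stem cell genes 13 fell and 1 rose (median -1.57, adjusted p = 0.00585, and adjusted p = 0.254 with an estimated correlation), with Cd34 at -2.91 ± 0.17 and Hlf at -2.92 ± 0.24. Of 11 Hox list genes 9 fell (median -1.68, adjusted p = 0.00288, and adjusted p = 0.254 with an estimated correlation), such as Hoxa9 (-1.60 ± 0.20). Of 15 dendritic cell and MHC class II genes 10 rose and 1 fell (median 2.03, adjusted p = 0.000427, and adjusted p = 0.299 with an estimated correlation). The cross-presenting dendritic cell receptor Xcr1 rose by 4.68 ± 0.37 and H2-Aa by 3.57 ± 0.27.

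Of 25 interferon genes 16 fell and none rose (18 fell adjusted over the list alone; median -1.61, camera adjusted p = 0.00288, and adjusted p = 0.57 with an estimated correlation). An example is the RNA sensor Ddx58 (-2.20 ± 0.38). Of 17 B lymphoid genes 7 fell and 1 rose (median -1.49, adjusted p = 0.0273, and adjusted p = 0.612 with an estimated correlation). Among them was the recombinase Rag2 (-4.60 ± 0.56), and the list call was lost without Jak2V617F 3 (adjusted p = 0.0612). Of 15 T and NK genes 3 rose and 1 fell (median 0.81, adjusted p = 0.0421, and adjusted p = 0.57 with an estimated correlation). That call was lost without Jak2V617F 2 (adjusted p = 0.219), WT 1 (adjusted p = 0.0946) or WT 3 (adjusted p = 0.111), with the stricter filter (0.166), with median-of-ratios scaling (0.0602) and by fry (0.222). Of 17 fibrosis and matrix genes 9 fell and 2 rose (median -2.25, adjusted p = 0.0132, and adjusted p = 0.254 with an estimated correlation), with Vim at -2.34 ± 0.13. Of 8 stroma genes 5 fell (6 adjusted over the list alone; median -2.10, adjusted p = 0.0142, and adjusted p = 0.254 with an estimated correlation). Of 27 cell cycle genes 11 rose and 3 fell (13 and 3 adjusted over the list alone; median 0.22, adjusted p = 0.0176, and adjusted p = 0.529 with an estimated correlation), such as the replication helicase gene Mcm4 (0.58 ± 0.08). Of 16 p53 targets 9 rose and 3 fell (median 0.81, adjusted p = 0.0142, and adjusted p = 0.254 with an estimated correlation), with the apoptosis effector Bax at 0.75 ± 0.09 and Perp at -3.01 ± 0.37. Of 16 JAK-STAT targets 5 rose and 3 fell (5 and 4 adjusted over the list alone; adjusted p = 0.352), with Stat5a at 0.73 ± 0.12 and the inhibitor of differentiation Id1 at -3.02 ± 0.32. TNF and NF-kB genes (3 rose and 4 fell of 19; adjusted p = 0.813), immediate early genes (2 rose and 3 fell of 20, 1 and 3 adjusted over the list alone, median 0.08, mean -0.01; adjusted p = 0.813), Polycomb and BAP1 genes (10 rose and 8 fell of 30, median 0.01, mean -0.07; adjusted p = 0.769) and cholesterol synthesis genes (4 rose and 7 fell of 20; adjusted p = 0.769) gave no list call. Tnf itself fell (-2.11 ± 0.34, adjusted p = 0.000266). Jak2 rose by 0.71 ± 0.08 (adjusted p = 1.84e-05). Egr1 rose by 1.55 ± 0.56 (adjusted p = 0.0436), a call lost without Jak2V617F 2 (0.0582), Jak2V617F 3 (0.162), WT 2 (0.119) or WT 3 (0.0696), and in a fit of both groups alone (0.0639), with a sex term (0.0656) or with the replicate block (0.062).

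In all, 8706 genes changed, 3965 higher and 4741 lower, of which 1168 and 2973 differed at least 2-fold. C2cd4a (ENSMUSG00000047990, chromosome 9, 67830489 to 67832330) was 43.4 ± 8.56 CPM in Jak2V617F and 0.23 ± 0.113 CPM in WT (7.52 ± 0.31), a fold that rests on few WT reads. The sialomucin podocalyxin, Podxl (ENSMUSG00000025608, chromosome 6, 31519488 to 31563981), was 364 ± 51.9 against 3.47 ± 2.36 CPM (6.72 ± 0.43). Plek2, a cytoskeletal pleckstrin of erythroid cells (6.03 ± 0.55), and the cytidine deaminase gene Cda (5.47 ± 0.41) rose with them. Among the largest falls were the macrophage sialic acid receptor Siglec1 (-5.21 ± 0.85) and Igll1 of the surrogate light chain (-5.20 ± 0.93).

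**Figure D3:**
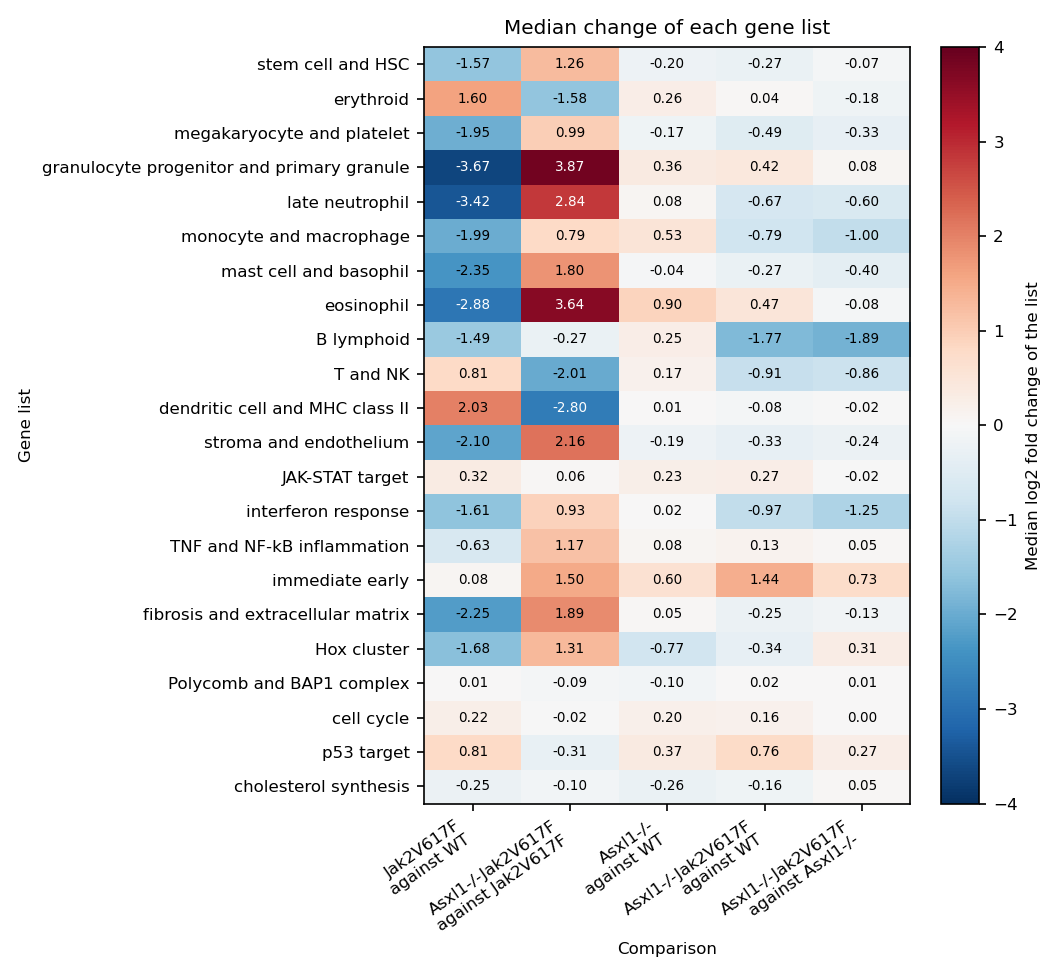
Median log2 fold change of each of the 22 gene lists (vertical) in the 5 comparisons (horizontal), written in each cell and coloured from blue (lower) to red (higher). Primary granule genes have a median of -3.67 in Jak2V617F against WT and 3.87 in Asxl1-/-Jak2V617F against Jak2V617F, and of 0.36 in Asxl1-/- against WT.

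In Asxl1-/- against WT single genes passed, but no lineage list did. Vasn, a membrane glycoprotein that binds TGF-beta, fell from 44.6 ± 8.20 to 5.94 ± 0.724 CPM (-2.91 ± 0.23, adjusted p = 0.000256), and the ciliary genes Ccdc39 (-2.27 ± 0.33) and Dnah17 (-2.26 ± 0.30) fell with it. Cpa3 rose by 1.27 ± 0.16, the proliferation antigen gene Mki67 fell (-0.74 ± 0.10) and Ogt, the X-linked O-GlcNAc transferase that binds BAP1, fell (-0.95 ± 0.12). These 6 genes kept their calls in every leave-one-out fit and with a sex term. Eif3j2 (3.42 ± 0.47) and Gapdh (2.33 ± 0.30) also rose, although both share sequence with near-identical copies and their counts are uncertain. Both calls were lost with the sex term.

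Of 30 Polycomb and BAP1 genes 6 fell and 3 rose (9 and 5 adjusted over the list alone; camera adjusted p = 0.284), among them the paralog Asxl2 (-0.49 ± 0.08), whose call was lost without Asxl1-/- 1 (adjusted p = 0.0748). Of 11 Hox list genes 3 fell (4 adjusted over the list alone; median -0.77, adjusted p = 0.11). Of 27 cell cycle genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.20, adjusted p = 0.0658), such as Ccnb2 (0.39 ± 0.09), whose call was lost without Asxl1-/- 1 (adjusted p = 0.103). Of 10 eosinophil genes 3 rose (median 0.90, adjusted p = 0.0658), of 20 immediate early genes 3 rose (median 0.60, adjusted p = 0.0785) and of 16 p53 targets 3 rose (5 adjusted over the list alone; median 0.37, adjusted p = 0.0785). Cholesterol synthesis (2 fell of 20, adjusted p = 0.182) and JAK-STAT targets (1 rose and 1 fell of 16, adjusted p = 0.333) had the same counts adjusted over the list alone. Of mast cell and basophil genes 1 of 12, Cpa3, rose (1 adjusted over the list alone, adjusted p = 0.561). Among stem cell genes 1 of 19 rose (adjusted p = 0.637), among megakaryocyte genes 2 of 22 fell (adjusted p = 0.561), among T and NK genes 1 of 15 rose (adjusted p = 0.523) and among fibrosis genes 1 of 17 rose (adjusted p = 0.561), with 0 calls in each adjusted over the list alone. Apart from Cpa3, all the named member calls in these lists other than the Polycomb and cell cycle ones, such as Ear2, Prg2, Ier2, Junb, Hoxb3 and Perp, were lost without Asxl1-/- 1 and, Ccnd2 apart, without Asxl1-/- 2, with adjusted p of up to 0.268 over all leave-one-out fits. In the 9 lists left, which hold the erythroid, primary granule, late neutrophil, monocyte, B lymphoid, dendritic, stroma, interferon and TNF genes, edgeR called 0 of 163 measured genes, where 7 were higher and 1 lower at an unadjusted p under the threshold and DESeq2 called 5 higher. Camera called no list here, and the estimated-correlation values lay at 0.904 or above. Some list tests passed when a library was left out. Without Asxl1-/- 1 these were eosinophil (0.0156), immediate early (0.0156), monocyte and macrophage (0.0188), p53 (0.0296), Hox (0.0499) and cell cycle (0.0499) genes. Cell cycle genes also passed without Asxl1-/- 2 (0.0359), WT 1 (0.0178) and WT 3 (0.0468), immediate early genes without WT 1 (0.017), and eosinophil (0.0055) and interferon genes (1.52e-05) without WT 3. With the replicate block eosinophil (0.0265), cell cycle (0.0265), immediate early (0.048) and interferon genes (0.048) passed.

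In all, 3664 genes changed, 1835 higher and 1829 lower, but 959 were at least 2-fold lower and 156 at least 2-fold higher. Of the 959, 662 were not protein-coding, as were 93 of the 156 and 3307 of the 16262 genes tested. With protein-coding genes alone, 327 were 2-fold lower and 52 higher. Both Asxl1-/- libraries had Y-linked reads and no WT library did, and with a sex term, which rests on Jak2V617F 2, 502 genes were called, 94 higher and 408 lower. The count was 288 without Asxl1-/- 1, 1407 without Asxl1-/- 2, 1929 without WT 2 and 2182 without WT 3. Jak2 rose by 0.40 ± 0.09 (adjusted p = 0.00955), lost without Asxl1-/- 1 (0.0764) or Asxl1-/- 2 (0.0662) and with the sex term (0.0914). Egr1 differed by 1.45 ± 0.61 (adjusted p = 0.121) and Tnf by 0.26 ± 0.34 (adjusted p = 0.613).

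The cells with both lesions were closer to WT than the Jak2V617F cells on the main axis. In Asxl1-/-Jak2V617F against WT, C2cd4a (6.03 ± 0.31), Podxl (124 ± 37.4 against 3.47 ± 2.36 CPM, 5.17 ± 0.41), Cda (4.19 ± 0.40) and Plek2 (4.19 ± 0.55) rose. These 4 were also among the largest rises in Jak2V617F against WT, a comparison with the same WT libraries. Of 20 immediate early genes 10 rose and none fell (12 adjusted over the list alone; median 1.44, camera adjusted p = 1.24e-06, and adjusted p = 0.47 with an estimated correlation). Among them were Junb (1.69 ± 0.21), Fos (2.70 ± 0.45) and the phosphatase gene Dusp1 (2.48 ± 0.40). Egr1 rose from 5.81 ± 2.96 to 41.7 ± 8.46 CPM (2.84 ± 0.58, adjusted p = 0.0177), a call lost without WT 2 (0.0578) or WT 3 (0.0549). Of 16 p53 targets 7 rose (12 adjusted over the list alone; median 0.76, adjusted p = 3.39e-05, and adjusted p = 0.245 with an estimated correlation). Pmaip1, which encodes the pro-apoptotic protein Noxa, rose by 2.98 ± 0.35, Gadd45a by 0.88 ± 0.13 and Perp by 1.61 ± 0.29. Of 27 cell cycle genes 5 rose (5 adjusted over the list alone; median 0.16, adjusted p = 0.000774, and adjusted p = 0.61 with an estimated correlation).

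Of 22 monocyte and macrophage genes 8 fell and 1 rose (11 and 2 adjusted over the list alone; median -0.79, camera adjusted p = 0.00558, and adjusted p = 0.61 with an estimated correlation), with Axl, a receptor for apoptotic cell uptake, at -4.17 ± 0.67. Outside the list, Siglec1 (-5.08 ± 0.85), the uptake receptors Mertk (-4.94 ± 0.82) and Timd4 (-5.26 ± 0.84) and the collagen gene Col14a1 (-6.31 ± 0.81) fell too, as did the eotaxin receptor Ccr3 (-5.76 ± 0.75). Of 17 B lymphoid genes 2 fell (11 adjusted over the list alone; median -1.77, adjusted p = 5.46e-06, and adjusted p = 0.61 with an estimated correlation). Both calls, Rag2 and Cd22, were lost without Asxl1-/-Jak2V617F 1, Asxl1-/-Jak2V617F 2, WT 2 or WT 3, with adjusted p of up to 0.0971 and 0.113. Of 22 megakaryocyte genes 7 fell (1 rose and 13 fell adjusted over the list alone; median -0.49, adjusted p = 0.00145, and adjusted p = 0.245 with an estimated correlation). Late neutrophil genes gave a lower list test (median -0.67, adjusted p = 0.0217, and adjusted p = 0.68 with an estimated correlation) with 0 of 19 genes called by edgeR, 6 lower at an unadjusted p under the threshold and 2 by DESeq2. It was lost without Asxl1-/-Jak2V617F 2 (adjusted p = 0.0726), without WT 2 (adjusted p = 0.103) and by fry (0.334). Of 25 interferon genes 1, Stat2, fell (0 adjusted over the list alone; median -0.97, adjusted p = 0.0318, and adjusted p = 0.68 with an estimated correlation). The list call was lost without Asxl1-/-Jak2V617F 1 (0.145), Asxl1-/-Jak2V617F 3 (0.064) or WT 3 (0.784) and by fry (0.381). Stat2 itself (-0.74 ± 0.19, adjusted p = 0.0299) kept its call in 1 of 6 leave-one-out fits, the one without WT 1.

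The other lists gave no call in Asxl1-/-Jak2V617F against WT. Of 16 JAK-STAT targets 4 rose (4 adjusted over the list alone; camera adjusted p = 0.0611, and 0.0341 by fry), with Pim1 at 1.44 ± 0.21. Of 19 TNF and NF-kB genes 6 rose and 2 fell (6 and 2 adjusted over the list alone; median 0.13, adjusted p = 0.0873), while Tnf did not pass (0.12 ± 0.31, adjusted p = 0.816). Of 10 eosinophil genes 3 rose and Ccr3 fell (the same adjusted over the list alone; median 0.47, mean -0.01, adjusted p = 0.139). Of 14 primary granule genes 2 rose (2 adjusted over the list alone; adjusted p = 0.0993), of 24 erythroid genes 1 rose (1 adjusted over the list alone; adjusted p = 0.536), and of 30 Polycomb and BAP1 genes 4 fell and 2 rose (the same adjusted over the list alone; median 0.02, mean -0.15, adjusted p = 0.557), with Ogt at -0.82 ± 0.11 and Cbx6 at -0.73 ± 0.13. Of T and NK genes Nkg7 rose and Cd4 fell (adjusted p = 0.177). Nkg7 was lost without Asxl1-/-Jak2V617F 1, Asxl1-/-Jak2V617F 2, WT 2 or WT 3 (adjusted p of up to 0.107) and in a fit of both groups alone (0.069), and Cd4 without Asxl1-/-Jak2V617F 1, WT 2 or WT 3 (up to 0.0603). Of mast cell and basophil genes 1 rose and 1 fell (adjusted p = 0.477), and of stroma genes 1 fell (adjusted p = 0.428). These 3 lists had the same counts adjusted over the list alone. Of fibrosis genes 2 fell (1 adjusted over the list alone, adjusted p = 0.419), and of stem cell genes 1 (adjusted p = 0.127) and of cholesterol synthesis genes 2 fell (adjusted p = 0.159), with 0 in both adjusted over the list alone. EdgeR called 0 of 15 dendritic cell genes (1 higher and 1 lower at an unadjusted p under the threshold, 0 by DESeq2) and 0 of 11 Hox list genes (4 lower, 1 by DESeq2). Left-out libraries brought some of these list tests past the threshold. These were stem cell (0.0372), Hox (0.0355) and eosinophil genes (0.0393) without Asxl1-/-Jak2V617F 2, and primary granule (0.00318), JAK-STAT (0.0219) and cholesterol synthesis genes (0.0107) without Asxl1-/-Jak2V617F 3. JAK-STAT genes passed without WT 1 (0.0491), primary granule (0.0496) and TNF genes (0.0186) without WT 2, and eosinophil (0.0372), T and NK (0.00595) and TNF genes (0.0392) without WT 3. Asxl1 fell (-0.75 ± 0.12, adjusted p = 0.0073), and Jak2 rose by 0.26 ± 0.08 (adjusted p = 0.0448), a call lost in each of the 6 leave-one-out fits, with adjusted p of up to 0.132, in a fit of both groups alone (0.0769) and with a sex term (0.0503). Of the 70 named genes that passed here, 28 kept their call in every leave-one-out fit. In all, 2449 genes changed, 1350 higher and 1099 lower, of which 124 and 559 differed at least 2-fold. The count was 1116 without Asxl1-/-Jak2V617F 1, 842 without Asxl1-/-Jak2V617F 2, 531 without WT 2 and 665 without WT 3.

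The comparison of Asxl1-/-Jak2V617F with Asxl1-/- asks what the activated kinase adds where Asxl1 is lost. It uses the same Asxl1-/- libraries as Asxl1-/- against WT. Opposite signs in both, as for Vasn, Cpa3 and Asxl2, thus rest partly on shared values. Both Asxl1-/- libraries carry Y-linked reads and no Asxl1-/-Jak2V617F library does, so sex and genotype cannot be told apart here. C2cd4a (4.65 ± 0.32), Cda (3.59 ± 0.45), Vasn (2.12 ± 0.23) and Pmaip1 (3.12 ± 0.42) rose, and Podxl rose from 9.06 ± 0.973 to 124 ± 37.4 CPM (3.77 ± 0.44). Pmaip1 was lost without Asxl1-/- 1 (adjusted p = 0.0513) and Podxl without Asxl1-/- 2 (adjusted p = 0.0632). Col14a1 (-7.11 ± 0.84), Ccr3 (-6.62 ± 0.78) and Cpa3 (-1.27 ± 0.16) fell. Of 22 monocyte and macrophage genes 9 fell and none rose (12 fell adjusted over the list alone; median -1, camera adjusted p = 5.54e-06, and adjusted p = 0.62 with an estimated correlation), with Axl at -5.09 ± 0.72 and Cd68 at -1.75 ± 0.29. Both were lost without Asxl1-/- 2 (adjusted p = 0.0685 and 0.0982). Of 17 B lymphoid genes 2 fell (9 adjusted over the list alone; median -1.89, adjusted p = 5.12e-08, and adjusted p = 0.62 with an estimated correlation). Of 22 megakaryocyte genes 3 fell and 1 rose (4 and 1 adjusted over the list alone; median -0.33, adjusted p = 0.0127, and adjusted p = 0.62 with an estimated correlation). Of 19 late neutrophil genes 1 fell (3 adjusted over the list alone; median -0.60, adjusted p = 0.00187, and adjusted p = 0.649 with an estimated correlation).

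Interferon genes had a lower list test (median -1.25, camera adjusted p = 0.000106, and adjusted p = 0.649 with an estimated correlation), with 0 of 25 genes called by edgeR, 8 lower at an unadjusted p under the threshold and 1 by DESeq2. Immediate early genes had a higher one (median 0.73, adjusted p = 0.00145, and adjusted p = 0.62 with an estimated correlation), with 0 of 20 called by edgeR, 7 higher at an unadjusted p under the threshold and 5 by DESeq2. Of 15 T and NK genes 1 fell (1 adjusted over the list alone; median -0.86, adjusted p = 0.0178, and adjusted p = 0.649 with an estimated correlation), lost without Asxl1-/-Jak2V617F 1 (0.0901) or Asxl1-/- 2 (0.187). By fry none of the 7 list calls of this comparison held, with adjusted p of 0.105 for megakaryocyte, 0.345 for late neutrophil, 0.0561 for monocyte and macrophage, 0.114 for B lymphoid, 0.299 for T and NK, 0.299 for interferon and 0.165 for immediate early genes. TNF and NF-kB (2 rose), p53 (1 rose, 3 adjusted over the list alone), eosinophil (2 fell), mast cell (1 fell), stroma (1 fell), fibrosis (1 fell), cell cycle (1 rose) and cholesterol synthesis genes (1 rose) gave no list call. List tests passed for p53 genes without Asxl1-/-Jak2V617F 2 (0.0129), for erythroid genes without Asxl1-/-Jak2V617F 3 (0.00676) and for TNF genes without Asxl1-/- 2 (0.0441). Of the 40 named genes that passed here, 9 kept their call in every leave-one-out fit. Across the 8 lists with 0 genes called by edgeR, which add the stem cell, erythroid, primary granule, dendritic, JAK-STAT and Hox genes to interferon and immediate early ones, 15 of 144 genes were higher and 17 lower at an unadjusted p under the threshold, and DESeq2 called 10 and 4. Adjusted over the list alone, 3 of 16 JAK-STAT targets rose (camera adjusted p = 0.478) and 1 of 15 dendritic cell genes fell (camera adjusted p = 0.845). Of 30 Polycomb and BAP1 genes 3 rose (3 adjusted over the list alone; adjusted p = 0.476), among them Asxl2 (0.51 ± 0.08), a call lost without Asxl1-/- 1 and without Asxl1-/- 2 (adjusted p of up to 0.104). Egr1 (1.39 ± 0.62, adjusted p = 0.235), Jak2 (-0.14 ± 0.09, adjusted p = 0.385) and Tnf (-0.14 ± 0.35, adjusted p = 0.854) did not pass. In all, 899 genes changed, 538 higher and 361 lower, of which 198 and 218 differed at least 2-fold (69 and 207 with protein-coding genes alone). The count was 526 without Asxl1-/-Jak2V617F 1, 359 without Asxl1-/-Jak2V617F 2, 165 without Asxl1-/- 1, 86 without Asxl1-/- 2, 1458 by DESeq2 and 52 with a sex term (51 higher and 1 lower). The balance of higher and lower genes was not stable, with 55 higher and 110 lower without Asxl1-/- 1 and 365 and 368 in a fit of both groups alone. C2cd4a, Pmaip1 and Vasn kept their calls with that term, while Podxl, Cda, Col14a1, Ccr3, Cpa3, Axl, Cd68 and Asxl2 lost theirs.

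The effect of Asxl1 loss was not the same on both backgrounds. Across 16262 genes the log2 fold changes of Asxl1 loss with and without Jak2V617F had r = 0.04 and rho = 0.04, and those of Jak2V617F with and without Asxl1 had r = 0.10 and rho = 0.05. These describe genes, which are not independent replicates, and the contrasts in each pair share no library. In each pair the contrast with Asxl1-/- libraries also differs in Y-linked reads, and r was not computed with a sex term. Genes higher after Asxl1 loss on both backgrounds numbered 366, against 450 for independent lists, and genes lower on both 364, against 363. Genes higher with Jak2V617F on both Asxl1 backgrounds numbered 120 against 131, and lower on both 224 against 105. Opposite calls for Jak2V617F numbered 151 against 157 (higher on the Asxl1-/- and lower on the WT background) and 32 against 88 (the reverse). For Asxl1 loss, 335 against 448 were higher on the Jak2V617F and lower on the WT background, and 422 against 364 the reverse. The interaction was called for 6764 genes, 3858 with a higher and 2906 with a lower effect of Asxl1 loss in the Jak2V617F background. The smallest adjusted p belonged to Erg, an ETS factor of stem cells and megakaryocytes (67.9 ± 5.04 CPM in Asxl1-/-Jak2V617F, 10.8 ± 0.652 in Jak2V617F, 79.3 ± 5.90 in Asxl1-/- and 90.1 ± 4.41 in WT; interaction 2.84 ± 0.14, adjusted p = 1.98e-06). The count was 4483 without Asxl1-/- 1 and 3079 with a sex term.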

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

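The 3 tests of the granulocyte and erythroid pattern, and the second length test and the test on protein-coding genes for the Asxl1-/- pattern, were chosen only after the results were seen. The sex term was added after the data were seen as well.

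The effect of Asxl1 loss differed between the Jak2V617F and the WT background for 6764 genes by the interaction term of edgeR's fit. The lists called in the interaction, by camera with the preset correlation, had median log2 values of 3.65 for primary granule, 2.78 for late neutrophil, 2.81 for eosinophil, 1.64 for stem cell, 1.5 for megakaryocyte, 1.46 for mast cell and basophil, 1.84 for Hox, -1.91 for erythroid, -2.32 for dendritic cell and MHC class II and -1.75 for T and NK genes. Their adjusted p was 0.435 to 0.466 with an estimated correlation, and the T and NK call was also lost by fry (adjusted p = 0.0803). Cell cycle genes (median -0.22, camera adjusted p = 0.0636) passed with median-of-ratios scaling (0.0428) and the block (0.0462). They also did without Asxl1-/-Jak2V617F 3 (0.0409), Jak2V617F 1 (0.041), Jak2V617F 2 (0.0299) or WT 1 (0.0317). Fits that leave 1 Asxl1-/- library are not listed here. By fry stroma (0.0106), fibrosis (0.00171) and p53 genes (0.0488) passed. By camera stroma genes passed without WT 1 (0.0467). The 10 genes of smallest adjusted p were Erg (2.84), Rab44 (3.87), Nin (2.62), Idh1 (2.42), Ikbke (3.47), Itih5 (3.66), Mcf2l (4.31), Tmx4 (2.34), Rab3d (2.88) and Rps6ka2 (3.22). Jak2 had an interaction of -0.85 ± 0.12 (adjusted p = 0.000273). Tnf had one of 1.97 ± 0.48 (adjusted p = 0.00776), which did not pass with a sex term (adjusted p = 0.122).

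The 6 libraries of a comparison of 3 with 3 make 10 splits, too few for a share under 0.05, so that a chance split is neither excluded nor shown. For Asxl1-/-Jak2V617F against Jak2V617F, 1 of 10 splits (the real one, 7209 genes) gave as many changed genes and the highest other gave 2. For Jak2V617F against WT, 1 of 10 did (8706 genes) and the others gave 0. For Asxl1-/-Jak2V617F against WT, 1 of 10 did (2449 genes) and the highest other gave 137.

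Granulocyte genes were lower and erythroid genes higher in Jak2V617F than in WT, and the reverse held for Asxl1-/-Jak2V617F against Jak2V617F. A few abundant genes distorting the scaling would move all genes alike, but the erythroid median lay 1.65 log2 units above the median of all genes in Jak2V617F against WT. A loss of granulocytic cells with all others kept in proportion would raise every other cell type alike. The mast cell and basophil median lay at -3.95 relative to the erythroid one, with 8 of 12 of its genes falling. Basophils are themselves granulocytes, so that value cannot decide. The stem cell list argues against such a loss only as far as its genes mark stem cells, and some, such as Cd34, also mark other progenitors. Its median was -1.57 against 1.60 for erythroid genes, with 13 of 19 genes falling and 1 rising. Both medians were known when the test was chosen. A swap between the 2 groups is argued against by Asxl1, whose lowest Jak2V617F level lay 31.4 CPM above its highest Asxl1-/-Jak2V617F level. A hypothesis from these same data is a c-kit+ fraction shifted from myeloid toward erythroid progenitors in Jak2V617F, and at most partly so in Asxl1-/-Jak2V617F. In Asxl1-/-Jak2V617F against WT, erythroid (median 0.04) and primary granule genes (median 0.42) gave no list call. Late neutrophil (median -0.67) and monocyte and macrophage genes (median -0.79) were called lower there by camera with the preset correlation. Such a shift does not account for the dendritic cell and MHC class II genes, of which 10 of 15 rose and 1 fell in Jak2V617F against WT (median 2.03) and 10 fell and 1 rose in Asxl1-/-Jak2V617F against Jak2V617F (median -2.80). The hypothesis as worded also leaves aside the megakaryocyte, stem cell and Hox lists. In Jak2V617F against WT, 16 of 22, 13 of 19 and 9 of 11 of their genes fell, and 0, 1 and 0 rose. Differences in cell preparation between groups were not tested. Counts of sorted erythroid and myeloid progenitors in the c-kit+ fraction of each genotype would test the hypothesis.

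In Asxl1-/- against WT, 959 genes were at least 2-fold lower and 156 at least 2-fold higher. Removing a trend of fold change with exonic length left 887 of the 959 at least 2-fold lower, which argues against that trend as the whole source, although the test written beforehand (rho = -0.15) fell between its bounds and left length undecided. The test by removing the trend had been put in its place after that value was seen, before both were kept. Non-coding RNA as the whole source is argued against, since with protein-coding genes alone 327 were 2-fold lower and 52 higher. More non-coding and unspliced RNA in the WT libraries stays open as a part. Non-coding and intronic gene models took at least 0.268 percentage points more of the counts in every WT library (0.635 to 0.789%) than in any Asxl1-/- library (0.328 to 0.366%). As 662 of the 959 lower genes were themselves not protein-coding (69%, against 20.3% of genes tested), that share largely restates the pattern. Unspliced RNA was not measured. The 959 genes were also low in level, with a median of 1.34 for their mean CPM. Across genes, log2 fold change rose with mean log2 CPM (Spearman rho = 0.35), and that trend was not tested as a source. With a sex term 284 genes were called 2-fold lower and 21 higher. The lower count was under the bound of 0.5 times 959 written beforehand for sex as a source, but the excess of lower over higher genes did not shrink as a ratio, 17 of the 959 lie on X or Y, 879 of the 959 still had a log2 change of -1 or lower, and the median SE rose from 0.48 to 0.74 while the median log2 change went from -2.08 to -2.14. That reading of the standard errors was made after the count was seen. They derive from the same F statistic as the calls, so they are not separate evidence. The sex term rests on Jak2V617F 2 alone. The non-coding share of every WT library also lay above those of Jak2V617F (0.491 to 0.595%) and Asxl1-/-Jak2V617F (0.464 to 0.577%). In Asxl1-/-Jak2V617F against WT, where no library carries Y-linked reads, 559 genes were 2-fold lower and 124 higher. With protein-coding genes alone these were 429 and 103. Whether they are the same genes was not tested. In Asxl1-/- against WT all Asxl1-/- and no WT libraries carry Y-linked reads, so sex, genotype and RNA content cannot be told apart there.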

How the results depend on the processing

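The sex term and the restriction to protein-coding genes were chosen after seeing the data, and all other alternatives before. No named gene that passed reversed in direction with other scaling, DESeq2, a fit of the compared groups alone, the block, the sex term or a library left out. No list that passed did with other scaling, the stricter filter, the block, fry, an estimated correlation or a library left out. Other alternatives were not run for them. The side with more genes changed in 3 comparisons. For Asxl1-/- against WT 1835 were higher and 1829 lower, a near tie, against 1703 and 1897 in a fit of both groups alone, 1611 and 1692 with no filter, 1296 and 1303 with protein-coding genes alone, 94 and 408 with the sex term, 78 and 210 without Asxl1-/- 1, 674 and 733 without Asxl1-/- 2, 847 and 1082 without WT 2, 1011 and 1171 without WT 3 and 156 and 959 at 2-fold. For Asxl1-/-Jak2V617F against Asxl1-/- it went from 538 and 361 to 365 and 368 in a fit of both groups alone, 55 and 110 without Asxl1-/- 1 and 198 and 218 at 2-fold, while the sex term gave 51 and 1. For Asxl1-/-Jak2V617F against WT it went from 1350 and 1099 to 124 and 559 at 2-fold. Requiring a 2-fold change by construction lowers the counts, to 3508 for Asxl1-/-Jak2V617F against Jak2V617F, 4141 for Jak2V617F against WT, 1115 for Asxl1-/- against WT, 683 for Asxl1-/-Jak2V617F against WT, 416 for Asxl1-/-Jak2V617F against Asxl1-/- and 3790 for the interaction. The sex term gave 502 for Asxl1-/- against WT, 52 for Asxl1-/-Jak2V617F against Asxl1-/- and 3079 for the interaction, and the cause was not tested. DESeq2 gave 1458 for Asxl1-/-Jak2V617F against Asxl1-/- and r = 0.01 for the effect of Jak2V617F across Asxl1 backgrounds, and the cause was not tested. That r was 0.04 with no filter and 0.15 in fits of the compared groups alone. Other scalings moved the share of higher calls by under 10 points.

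Leaving out 1 library gave 5839 to 7062 genes for Asxl1-/-Jak2V617F against Jak2V617F, 7408 to 8608 for Jak2V617F against WT, 288 (without Asxl1-/- 1) to 4376 (without WT 1) for Asxl1-/- against WT, 531 (without WT 2) to 3493 (without WT 1) for Asxl1-/-Jak2V617F against WT, 86 (without Asxl1-/- 2) to 751 for Asxl1-/-Jak2V617F against Asxl1-/- and 4483 (without Asxl1-/- 1) to 7016 for the interaction. Where 1 Asxl1-/- library is left, it is assumed to vary like the other groups. The agreement r ranged from 0.01 to 0.09 for Asxl1 loss and from 0.06 to 0.14 for Jak2V617F. Of the named genes that passed, 103 of 107 kept their call in every such fit for Asxl1-/-Jak2V617F against Jak2V617F and 104 of 107 for Jak2V617F against WT, but 8 of 52 for Asxl1-/- against WT, 28 of 70 for Asxl1-/-Jak2V617F against WT and 9 of 40 for Asxl1-/-Jak2V617F against Asxl1-/-.

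Of 132 list tests 56 passed, 53 to 64 when 1 library was left out, 54 with the stricter filter, 50 by fry and 0 with an estimated correlation, where 8 had an unadjusted p under the threshold. The estimated correlations lie above the preset one, which widens the test.

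Replicate numbers do not pair these samples: over 15 same-numbered pairs the correlation of deviations ran from -0.20 to 0.17, was over 0.1 in 4, and 5 of 11 libraries correlated best with their own number. With the replicate block 585 genes changed in Asxl1-/-Jak2V617F against Asxl1-/-, and the other counts stayed within 1.5 times. The block ended 2 list calls, stroma (adjusted p = 0.057) and fibrosis (adjusted p = 0.057) in Asxl1-/-Jak2V617F against Jak2V617F. It added 7, so that 61 passed: interferon in that comparison (0.0374), eosinophil (0.0265), cell cycle (0.0265), immediate early (0.048) and interferon (0.048) in Asxl1-/- against WT, primary granule in Asxl1-/-Jak2V617F against WT (0.0313) and cell cycle in the interaction (0.0462). The cause was not tested. Among the 639 named gene and comparison results, which include those that did not pass, the block ended 24 calls and added 14. At 16198011 to 19196283 counts, genes near 1 CPM hold few reads, which limits what can be called among them.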

Other observations

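The resident macrophage list was written after the falls of 8 of its 18 genes were seen (Siglec1, Mertk, Timd4, Axl, C1qa, C1qc, Fcna and Cd68), and the heat shock list before its own values were seen. The 8 genes were left out of the counts below after the list was seen to move.

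Genes of resident macrophages, which take up dying cells and recycle iron in the marrow, were lower in both Jak2V617F genotypes than in WT. Of the 10 other genes 9 fell in Asxl1-/-Jak2V617F against WT (10 adjusted over the list alone; median log2 -3.29), 9 in Asxl1-/-Jak2V617F against Asxl1-/- (10 adjusted over the list alone; median -4.16) and 9 in Jak2V617F against WT (10 adjusted over the list alone; median -2.10). The comparison with Asxl1-/- is fragile, with 5 genes falling without Asxl1-/-Jak2V617F 1, 5 without Asxl1-/-Jak2V617F 2, 5 without Asxl1-/- 1, 1 without Asxl1-/- 2 and none with a sex term (median -2.84). In Asxl1-/-Jak2V617F against WT 5 fell without Asxl1-/-Jak2V617F 1, 5 without Asxl1-/-Jak2V617F 2, 6 without WT 2, 6 without WT 3 and 9 with a sex term. In Jak2V617F against WT 8 to 10 fell in all settings. Examples in Asxl1-/-Jak2V617F against WT were the haemoglobin scavenger receptor Cd163 (-3.17 ± 0.36), the haem oxygenase gene Hmox1 (-3.34 ± 0.60), the iron exporter Slc40a1 (-0.93 ± 0.18) and the macrophage transcription factor Spic (-4.40 ± 0.77). Cd163 was -1.95 ± 0.33 in Jak2V617F against WT. In Asxl1-/- against WT the median was 0.83, and -0.38 with a sex term, and at most 1 gene passed in any setting. In Asxl1-/-Jak2V617F against Jak2V617F 2 fell (median -0.95), with 5 without Jak2V617F 3, 1 without Asxl1-/-Jak2V617F 2 and none without Asxl1-/-Jak2V617F 1, without Jak2V617F 2, with a sex term or with no filter. Siglec1 was 57.5 ± 48.7 CPM in WT and 99.3 ± 52.3 in Asxl1-/-, so its level varied widely between libraries of those groups. The monocyte and macrophage list shares C1qa, C1qc, Axl and Cd68 with the 8 genes left out, and C1qb, Adgre1 and Vcam1 with the 10 counted. The counted genes were therefore not all untested before. A CD117 bead enrichment would be expected to hold few such cells.

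Immediate early genes were higher in Asxl1-/-Jak2V617F than in WT (10 of 20 rose, median 1.44). A single library with a high level is argued against as the source, since the list median stayed at 1.11 or above in every leave-one-out fit, although the number of the 10 genes still past the threshold was 4 without WT 2 and 4 without WT 3. A general stress response to cell handling stays open: the heat shock list had a median of 0.67 with 2 of 11 genes rising in Asxl1-/-Jak2V617F against WT, between what such a response would give and what its absence would. The number rising was 1 without WT 2 and 4 by DESeq2 or with a sex term. Heat shock genes were also higher in Jak2V617F against WT, where 6 of 11 rose (median 0.71), while 2 of 20 immediate early genes rose and 3 fell there. In Asxl1-/- against WT the heat shock median was 0.61 with 1 of 11 rising (5 in a fit of both groups alone, and a median of -0.41 with none rising with a sex term), and 3 of 20 immediate early genes rose. Without a sex term the heat shock medians against WT thus lay between 0.61 and 0.71 in the 3 genotypes, while the immediate early medians were 1.44 in Asxl1-/-Jak2V617F, 0.08 in Jak2V617F and 0.60 in Asxl1-/-. The 2 lists parted in Asxl1-/-Jak2V617F against Jak2V617F, where 13 of 20 immediate early genes rose. There 0 of 11 heat shock genes rose and 4 fell (median -0.45). Against Asxl1-/- the heat shock median was 0.09 and the immediate early one 0.73, with 0 genes of either list called. No time from marrow collection to lysis is given in the sources used here, so handling and genotype cannot be told apart for these genes.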
